A study of Mus musculus with 48 samples.

How the data were processed

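Total RNA was sequenced from epidermal cell suspensions of adult mice (18 to 25 weeks old) and aged mice (80 to 90 weeks old). Mice were sampled at 6 Zeitgeber times (ZT, hours after lights on), ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. Each of the 12 groups of age and time held 4 libraries, which makes 48 libraries, 24 per age. Libraries were made with a stranded total RNA kit with removal of ribosomal RNA, so that unspliced and non-polyadenylated transcripts were counted too. Strain and sex are not given in the sources used here. A rise or fall with age thus means a difference between these adult and aged libraries, which may include a difference in genetic background. Reads of the X-linked Xist numbered between 85452 and 144484 in every library, while the Y-linked Ddx3y, Uty and Eif2s3y had at most 7, 17 and 2. The labels do not say that the replicates are separate animals, so each p-value measures the spread between these samples.

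The values used were raw counts per gene deposited by the authors, as whole numbers for 24996 Entrez gene identifiers. The tools named for their processing were Trim Galore, STAR 2.7.10a and featureCounts with the mouse genome mm10 (GRCm38); the strand setting and the annotation are not given in the sources used here. Gene symbols and coordinates came from the GRCm38 annotation of RefSeq, which named 23476 of the identifiers. The other 1520 held 3.66% of all counts and are called Entrez followed by their number. Total counts per library ran from 40761084 to 49229498, with a median of 45299730. A gene with no count in a library of the lowest depth could thus hold up to 3 counts in 40761084, counting error only.

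Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with its filter on low counts, set to a minimum count of 10 and a minimum total of 15 over the 12 groups, which left 18044 genes. Library sizes were scaled by the trimmed mean of M values. Robust quasi-likelihood fits were made with 1 mean per group (36 residual degrees of freedom) and with a 24 h cosine per age (42 degrees of freedom). The typical biological coefficient of variation was 18%. The first model gave the age effect over all times with each time weighted equally, the age effect at each time, and a joint test of whether the age effect differed between times. The second gave the 24 h rhythm in each age and a test of whether the rhythms differed. Every p-value per gene is from edgeR's two-sided quasi-likelihood F test, and adjusted p-values follow Benjamini and Hochberg over the 18044 genes. A gene was called when its adjusted p was under 0.05. Fold changes are log2 ratios of aged over adult with their standard error (SE), amplitudes are log2 distances from mean to peak, and log2 CPM, counts relative to the scaled library size, used a prior count of 2.

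In total 45 gene lists for pathways and cell types were tested. For age, camera in limma 3.58.1 compared the members of a list with all other genes, with a preset correlation of 0.01 and again with a correlation estimated for each list. For rhythm, each list's mean of centred log2 CPM was fitted with a 24 h cosine and tested by permuting the times of libraries within an age 100000 times, or the ages within a time for the difference. Both sets of p-values were adjusted over the 45 lists. Lists share some genes; the heat shock list shares 5 members with the list of cold and temperature responsive genes. Counts of members are given over all genes tested and adjusted over the list alone.

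The lists, comparisons, tests and most alternatives were chosen before the data were examined, as was the rule for which genes are named. Named genes for age had an adjusted p under 0.05, a mean log2 CPM of at least 0 and the same sign at all 6 times, and were the 10 with the largest rise and the 10 with the largest fall. Named rhythmic genes were the 10 with the largest amplitude in each age, under the same limits on adjusted p and mean. For the difference of rhythms the 10 genes with the smallest adjusted p were named, and for age by time the 5 with the smallest p. From each list up to 4 members with the smallest p were named. Arntl, Yap1 and the members of the core clock list were always included. A few of the genes that the rule selects are not reported here. Symbols of predicted genes (Gm with a number, ending in Rik, or LOC) were left out of the rankings and kept in the counts. Genes named outside this rule are said to be so.

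Alternatives were DESeq2 1.42.0 with its own size factors, its size factors within edgeR, limma on log2 CPM, no filter and a stricter filter (1 CPM in at least 24 libraries), a stricter threshold of 0.01, minimum sizes, fits to parts of the samples, surrogate variables from sva 3.50.0, the replicate number as a block, and leaving out each library in turn. After seeing the data, fits without ZT20, without certain libraries, without small RNAs, with 2 surrogate variables and with list means for cell types as covariates were added. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Reads were not remapped, and splicing and allele-specific reads were not analysed here.

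The procedure was tested on simulated data with the same number of libraries and the same dispersions, with 200 changed genes in each simulation. Genes were drawn independently of each other, unlike in the real libraries, where many genes vary together. Recovery and false calls may thus differ in the real data. For age over all times it recovered 56% of 50 genes changed 1.25-fold, 82% of those changed 1.5-fold and 98% of those changed 2-fold, with 12 false calls among 180. At a single time it recovered 54% of genes changed 1.5-fold and 62% of those changed 2-fold. For rhythm in adult it recovered 44% at an amplitude of 0.25 and 84% at 0.5. For a rhythm present in adult and lost in aged it recovered 34% at 0.25 and 60% at 0.5. The median error of the peak time was 0.279 h.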

Results

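Cadps2, which primes secretory vesicles for release, rose with age over all times by a log2 fold change of 2.74 (SE 0.08; adjusted p = 2.2e-26, edgeR), from 1.31 CPM in adult to 8.74 CPM in aged libraries (n = 24 each). The serpin Serpinb6d rose by 2.47 (SE 0.26) and the zinc finger gene Zmat4 by 2.21 (SE 0.18). Casp12, an inflammatory caspase, rose by 1.52 (SE 0.10), and the type I BMP receptor Bmpr1b by 1.54 (SE 0.19). Akr1c13 (a ketosteroid and xenobiotic reductase), Pid1 (an adaptor that dampens insulin signalling), Egr4 (an immediate early transcription factor) and Abca4 (a lipid transporter) rose by 1.75, 1.73, 1.49 and 1.32. Thbs1, a matrix glycoprotein, rose by 1.40 (SE 0.29; adjusted p = 3.5e-04), from 219 to 524 CPM.

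Among the falls, Peg3, an imprinted zinc finger gene, fell by 2.30 (SE 0.13), from 8.84 to 1.78 CPM. Fgf18, which holds hair follicle stem cells in their resting phase, fell by 1.91 (SE 0.11; adjusted p = 1.1e-16) and lies on chromosome 11 from 33116970 to 33147400 (GRCm38). Myoc (an extracellular glycoprotein) fell by 1.95 (SE 0.20), Car6 (a secreted carbonic anhydrase) by 1.83 (SE 0.42), and the ribosomal protein retrogene Rps4l by 1.78 (SE 0.08). Entrez100504453, which has no symbol, fell by 2.07 (SE 0.12). Tmem254a, Tmem254b and Tmem254c each fell by 1.91 to 1.94, but they are near-identical copies that share reads, so which of them changed is uncertain. Krt76, a keratin of oral and differentiating epithelium, fell by 4.00 (SE 1.29; adjusted p = 0.0267), and did not pass without any 1 of 4 adult libraries (ZT4 replicate 4, ZT12 replicates 3 and 4, ZT16 replicate 3; adjusted p up to 0.279).

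In all, 3061 genes were higher and 2915 lower in aged than in adult epidermis of the 18044 tested. Without the ZT20 libraries 1718 were higher and 1754 lower, which shared 54.1% and 56.9% of the calls made with all libraries. Most differences were small: 734 rises and 409 falls reached a log2 fold change of 0.5, and 142 and 94 reached 1. Of the genes called, 3110 had the same sign at all 6 times. The transcripts of the genes in the series title did not pass the test. Arntl (which encodes BMAL1) had a log2 fold change of -0.05 (SE 0.06; adjusted p = 0.572) and Yap1 of -0.04 (SE 0.03; adjusted p = 0.349) in edgeR's test. In 28 genes every adult library lay apart from every aged library, where chance gives such a separation of 24 from 24 libraries a share of 6.2e-14 per gene. These genes, singled out after their values were seen, included the mitochondrial transhydrogenase Nnt (a rise of 1.25, SE 0.06) and the inflammatory caspases Casp1 (0.80) and Casp4 (0.75). Casp1, Casp4 and Casp12 lie next to each other on chromosome 9, between 5298517 and 5373034 (GRCm38). Their rises may thus not be independent of each other. The 28 genes also included Wdfy1, an endosomal adaptor (0.72), and the BMP antagonist Nog (a fall of 1.21). Of the genes named above, Cadps2, Casp12, Akr1c13, Peg3, Fgf18, Rps4l, Entrez100504453 and Tmem254a to Tmem254c were among the 28 too. For all of them a difference in genetic background cannot be separated from age. Ide, the insulin-degrading enzyme, fell by 0.94 (SE 0.07), but 2 adult libraries lay within the aged range. Its median was 219 CPM in adult and 109 CPM in aged. Fgfbp3, also on chromosome 19 and also chosen after its values were seen, fell by 1.29 (SE 0.10). For Fgfbp3 too, 2 adult libraries lay within the aged range. Between these genes lie Btaf1, which fell by 0.23, and Cpeb3, which did not pass (-0.02, adjusted p = 0.896, edgeR).

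**Figure D1:**
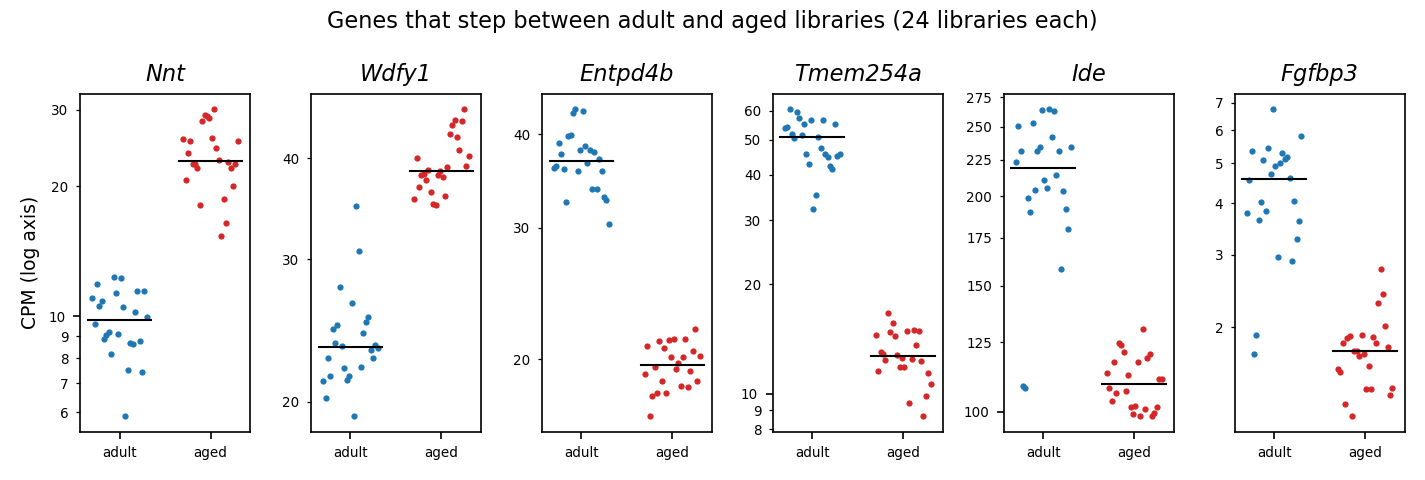
CPM on a log axis for Nnt, Wdfy1, Entpd4b, Tmem254a, Ide and Fgfbp3 in the 24 adult and 24 aged libraries (points, 1 per library; lines, medians). Nnt spans 5.87 to 12.3 CPM in adult and 15.3 to 30.2 CPM in aged, and 2 adult libraries lie at the aged level of Ide.

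The list of hair follicle stem cell and outer root sheath genes fell most clearly: 13 of 20 members were lower and 0 higher (also 13 and 0 when adjusted over the list alone), with a median of -0.46. Its camera adjusted p was 6.3e-09, and 0.541 with an estimated correlation. Besides Fgf18, the root sheath keratins Krt79 and Krt17 each fell by 0.69 (SE 0.08 and 0.09), the stem cell surface marker Cd34 by 0.93 (SE 0.12) and the growth factor Bmp6 by 1.01 (SE 0.15). Of 29 differentiated keratinocyte genes 16 were lower and 2 higher, the same counts when adjusted over the list alone (camera adjusted p = 7.8e-05, and 0.830 with an estimated correlation). The cornified envelope precursor Ivl fell by 0.81 (SE 0.11), the desquamation protease Klk7 by 0.98 (SE 0.16) and Krt80 by 0.47 (SE 0.07), while the crosslinking enzyme Tgm3 rose by 0.94 (SE 0.14). In the antimicrobial and alarmin list 3 of 11 members were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.049, and 0.830 with an estimated correlation). This call was lost without any 1 of 20 libraries, and without ZT20 (0.0529). The defensins Defb1 and Defb6 fell by 0.47 and 0.54 and the skin phospholipase Pla2g2f by 0.50, and Bst1, an ectoenzyme of leukocytes, rose by 0.61.

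Immediate early and dissociation genes were higher in aged, with 17 of 23 members up and 1 down (18 and 1 when adjusted over the list alone). The camera adjusted p was 1.7e-05, and 0.830 with an estimated correlation. Over the 3000 most variable genes, differences between libraries of the same group followed several lists. Principal component 1 (36.6%) went with dermal fibroblast (r = -0.95), anagen (-0.90) and hair follicle stem cell lists (-0.77). Component 2 (18.5%) went with Langerhans cell (0.87), NF-kB (0.85), immediate early (0.83) and differentiated keratinocyte lists (-0.75). For these lists a different mixture of cells was not told apart from changes within cells. The growth-response factor Egr3 rose by 0.60 (SE 0.10), and the AP-1 subunits Fosb and Fosl1 by 0.63 (SE 0.12) and 1.45 (SE 0.30). Glucocorticoid response genes rose in 7 of 17 cases with 0 falls, also when adjusted over the list alone (camera adjusted p = 0.049, and 0.909 with an estimated correlation). At single times this list passed only at ZT20, and the call over all times was lost without the ZT20 libraries (0.710), without the aged ZT20 replicates 1 and 2 (0.25) and without any 1 of 24 libraries. Fkbp5, a chaperone induced by the glucocorticoid receptor, rose by 1.01 (SE 0.17; 0.72 without ZT20), and the transcription factors Klf9 and Zbtb16 by 0.45 and 0.47. DNA repair genes were up in 10 of 26 cases and down in 1, and up in 11 when adjusted over the list alone (camera adjusted p = 0.049, and 0.983 with an estimated correlation). It was lost without any 1 of 27 libraries, without ZT20 (0.0529) and with the replicate number as a block (0.0542). The damage sensor Ddb2 rose by 0.21 (SE 0.05) and Brca2, which acts in homologous recombination, by 0.36 (SE 0.10). In the core clock list 12 of 19 members were higher and 2 lower, with 14 and 2 when adjusted over the list alone (camera adjusted p = 0.0135, and 0.736 with an estimated correlation; 0.0529 without ZT20). The repressors Per1, Per2 and Per3 rose by 0.42, 0.47 and 0.36, the output factor Tef by 0.28 (SE 0.06), and Clock by 0.15 (SE 0.03). Cry1 fell by 0.14 (SE 0.05; adjusted p = 0.0447, edgeR), a call lost without any 1 of 33 libraries.

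In the unfolded protein response list 11 of 18 members fell and 2 rose, with 12 falls when adjusted over the list alone (camera adjusted p = 0.0126, and 0.830 with an estimated correlation; 0.0529 without ZT20). Sdf2l1 and the disulfide isomerases Pdia6 and Pdia4, which fold proteins in the endoplasmic reticulum, fell by 0.47, 0.24 and 0.20, while the stress transcription factor Atf4 rose by 0.28. Heat shock genes fell in 8 of 16 cases and rose in 1, with 9 falls when adjusted over the list alone (camera adjusted p = 0.0225, and 0.830 with an estimated correlation). The list passed at ZT0 and ZT20 alone, with medians of 0.02 to 0.03 at ZT4, ZT8 and ZT12. At ZT16 its median was -0.14 (camera adjusted p = 0.0773). It did not pass over all times without the ZT20 libraries (0.374) or without the aged ZT20 replicates 1 and 2 (0.109). That aged pair was chosen by its low values on this list. The small heat shock proteins Hspb1 and Hspb8 fell by 0.40 (SE 0.06) and 0.24 (SE 0.05), and Dnajb1 rose by 0.30. Of 21 autophagy and lysosome genes 11 fell and 1 rose, with 12 falls when adjusted over the list alone (camera adjusted p = 0.0296, and 0.830 with an estimated correlation). The cathepsin Ctsd fell by 0.42 (SE 0.07) and Ctsl rose by 0.50 (SE 0.09). Mitochondrial oxidative phosphorylation genes fell in 10 of 30 cases and rose in 0, also when adjusted over the list alone (camera adjusted p = 0.0135, and 0.983 with an estimated correlation). The changes were small, such as 0.11 for Ndufv1 and 0.22 for Ndufa4, which encode complex I and complex IV subunits.

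Hippo pathway genes fell in 5 of 18 cases and rose in 0, also when adjusted over the list alone (camera adjusted p = 0.0392, and 0.830 with an estimated correlation; 0.0574 without ZT20). The YAP-binding scaffold Amot fell by 0.34 (SE 0.07), and the TEAD cofactors Vgll4 and Vgll3 by 0.22 and 0.31. The YAP/TAZ target signature did not pass over all times (camera adjusted p = 0.752, edgeR calls 5 higher and 3 lower of 20, also when adjusted over the list alone). Within it the receptor kinase Axl rose by 0.20 (SE 0.03) and the phosphatase Ptpn14 by 0.24 (SE 0.06), while the ectonucleotidase Nt5e fell by 0.22. The inflammatory cytokines and chemokines moved both ways, with 4 of 25 members higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.961). The inflammasome substrate Il18 rose by 0.78 (SE 0.12) and the chemokine Ccl20 by 0.67 (SE 0.17), while the monocyte chemokine Ccl7 fell by 0.88 (SE 0.20) and Il1f8 by 0.70 (SE 0.19). The NF-kB response had 8 higher and 2 lower of 20, with 9 and 3 when adjusted over the list alone (camera adjusted p = 0.109). The feedback regulators Zc3h12a, Nfkbiz and Tnfaip3 rose by 0.50, 0.32 and 0.53. The interferon response did not pass (camera adjusted p = 0.752), with rises of Xaf1 (0.25), Dhx58 (0.36) and Irf7 (0.42) and a fall of 0.78 for the chemokine Cxcl10.

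**Figure D2:**
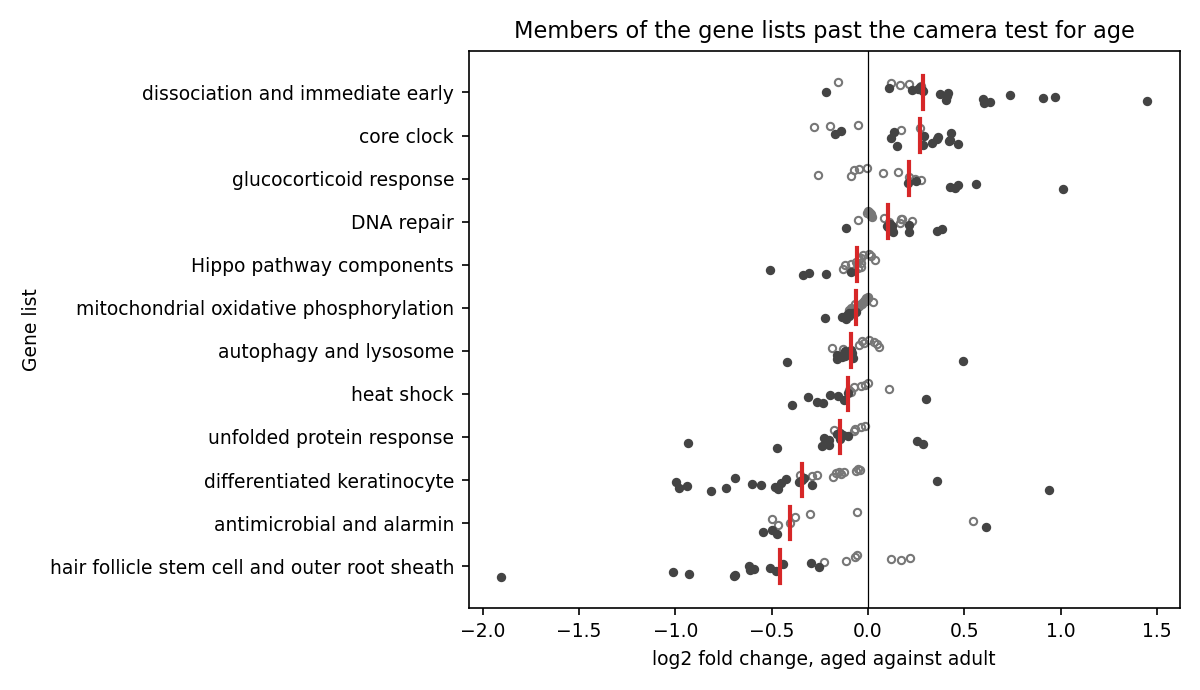
Log2 fold change, aged over adult, of each member of the 12 lists past the camera test with the preset correlation (filled points, past edgeR's test; open points, not; red bars, medians). The hair follicle stem cell and outer root sheath list has a median of -0.46, and 0 of the 12 lists passed with an estimated correlation.

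At single times the age effect was counted at 804 genes at ZT0 (440 higher, 364 lower), 114 at ZT4, 395 at ZT8, 199 at ZT12, 355 at ZT16 and 3616 at ZT20 (1721 higher, 1895 lower), with 4 libraries per age. Fgf18 passed at all 6 times, with falls between 1.37 at ZT16 and 2.33 at ZT0. With any 1 library left out the counts ranged from 410 to 1067 at ZT0, 50 to 131 at ZT4, 78 to 1179 at ZT8, 78 to 1312 at ZT12, 146 to 621 at ZT16 and 1821 to 3886 at ZT20. Of 35 splits of the libraries of one time, the split by age included, 2 at ZT8 and 8 at ZT12 gave at least the real count. The highest counts in the others were 2210 and 4851 genes. The ZT20 count was 457 without the aged ZT20 replicates 1 and 2, and 582 without the adult ZT20 replicates 1 and 2, the lowest for each age. The other pairs of aged ZT20 libraries gave 1161 to 1392, and 4194 without replicates 3 and 4, and the other adult pairs gave 942 to 1365, and 2996 without replicates 3 and 4.

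The lists at single times were tested after the data were seen. At ZT20 the glucocorticoid response rose in 12 of 17 members (14 when adjusted over the list alone) with 0 falls and a median of 0.93 (camera adjusted p = 4.4e-08, and 0.163 with an estimated correlation). Fkbp5 rose by 2.49 (SE 0.42), Klf9 by 1.29 (SE 0.22) and Per1 by 1.34 (SE 0.26). Cholesterol synthesis fell in 13 of 21 members (14 over the list alone) and rose in 1 (camera adjusted p = 4.4e-08, and 0.469 with an estimated correlation), with Nsdhl down by 0.69 (SE 0.11) and Mvd by 0.99 (SE 0.21). Heat shock genes fell in 9 of 16 cases (10 over the list alone) with 0 rises (camera adjusted p = 2.9e-07, and 0.238 with an estimated correlation). The chaperone cofactors Chordc1 and Cacybp fell by 0.64 and 0.68, and the cold-inducible RNA-binding proteins Rbm3 and Cirbp rose by 1.00 (SE 0.14) and 0.98 (SE 0.18). The unfolded protein response fell in 9 of 18 cases with 0 rises (9 and 1 over the list alone; camera adjusted p = 4.5e-07, and 0.238 with an estimated correlation), with Hsp90b1 down by 0.82 (SE 0.13). Core clock genes rose in 9 of 19 cases with 0 falls (11 and 1 over the list alone; camera adjusted p = 1.9e-04, and 0.163 with an estimated correlation), among them Tef by 0.79 and Ciart by 1.05. Differentiated keratinocyte genes fell in 16 of 29 cases (20 over the list alone) and rose in 1 (camera adjusted p = 2.4e-07, and 0.597 with an estimated correlation). Immediate early and dissociation genes rose in 13 of 23 cases (16 over the list alone) and NF-kB response genes in 8 of 20 (12), each with 0 falls (camera adjusted p = 3.05e-07 and 1.8e-04, and 0.597 for both with an estimated correlation). The Langerhans cell list was higher with a median of 0.84, on 2 of 20 members called (1 over the list alone; camera adjusted p = 0.0027, and 0.784 with an estimated correlation). In all 15 lists passed at ZT20, and 0 with an estimated correlation.

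A pair of aged libraries stood apart in several of these lists. In the aged ZT20 replicates 1 and 2 the mean of the cholesterol list was -0.716 and -0.599, against 0.020 and 0.009 in the other two and 0.035 to 0.289 in adult. The unfolded protein response stood at -0.380 and -0.346 against 0.119 and 0.096 (adult 0.225 to 0.369). The glucocorticoid response stood at 1.06 and 1.20 against 0.540 and 0.010 (adult -0.564 to 0.152). Without this pair, camera still ranked the same lists as changed in the same directions: glucocorticoid (adjusted p = 0.00163), cholesterol (0.0171), unfolded protein response (0.00504) and heat shock (0.0089). With an estimated correlation none of these passed (0.664 to 0.697). Their medians went from 0.93 to 0.44, from -0.54 to -0.29, from -0.44 to -0.23 and from -0.33 to -0.25. The members called fell to 0 of 17, 1 of 21, 4 of 18 and 1 of 16, those of the core clock from 9 to 1, and the lower differentiated keratinocyte genes from 16 to 1.

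At ZT0 the hair follicle stem cell and outer root sheath list fell in 8 of 20 members (15 over the list alone) with a median of -0.71 (camera adjusted p = 7.7e-12, and 0.234 with an estimated correlation), with Bmp6 down by 1.75 (SE 0.37). It was 1 of 16 lists past the test at ZT0, all lower in aged, and 0 passed with an estimated correlation. Among the others were Langerhans cell (median -0.92, camera adjusted p = 2.5e-04), dermal fibroblast (-1.08, 0.0059) and macrophage genes (-0.70, 0.0229), each at 0.911 with an estimated correlation. At ZT4, ZT8, ZT12 and ZT16 the number of lists past the test was 5, 16, 13 and 11, again 0 with an estimated correlation. Some moved in opposite directions. The Langerhans cell list was higher at ZT8 (median 0.87, camera adjusted p = 4.8e-05, and 0.732 with an estimated correlation) and lower at ZT16 (-1.30, 3.3e-08 and 0.746), with 0 members called at either time over all genes. Adjusted over the list alone, 0 members passed at ZT8 and 11 of 20 were lower at ZT16. YAP/TAZ targets were higher at ZT8 (0.24, 0.0186 and 0.732) and lower at ZT16 (-0.19, 0.0105 and 0.746), with 1 of 20 members called at ZT8 (4 when adjusted over the list alone) and 0 at ZT16 (also 0).

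**Figure D3:**
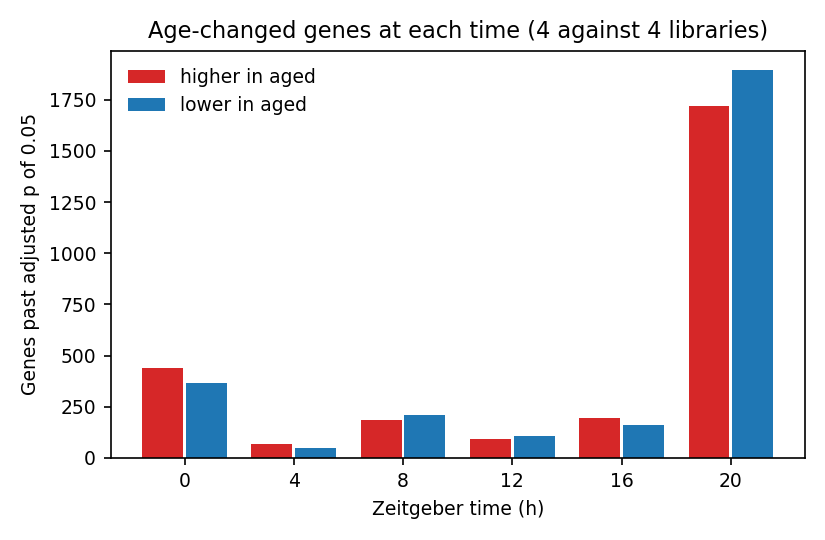
Number of genes higher and lower in aged than in adult epidermis at each Zeitgeber time in hours (bars; edgeR adjusted p under 0.05, 4 libraries per age and time). ZT20 has 1721 genes higher and 1895 lower, and ZT4 has 66 and 48.

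The age effect differed between times in 51 genes (3087 at an unadjusted p under 0.05, and 659 by DESeq2), among them 8 of the 109 small nucleolar RNAs tested. Snord17, which guides modification of ribosomal RNA, was higher in aged at ZT0 by 1.38 (SE 0.20) and lower at ZT8 by 0.75 (SE 0.20; adjusted p over times = 0.00169, edgeR). Snora81 and Snord15a, also guide RNAs, showed estimates of 1.34 and 1.22 at ZT0 and of -0.55 and -0.72 at ZT8. Scarna6, a guide RNA of Cajal bodies, had 0.75 at ZT0 and -0.55 at ZT8, and Entrez100503942 had 0.54 at ZT0. Leaving out the aged ZT0 replicate 1 lowered the count to 11, and leaving out the aged ZT12 replicate 3 raised it to 266.

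The core clock was rhythmic in both ages. Arntl had an amplitude of 1.05 (SE 0.07) in adult and 1.06 (SE 0.07) in aged, with peaks at ZT23.2 and ZT23.6. Its partner paralogue Npas2 peaked at ZT23.2 and ZT23.9 with amplitudes of 1.52 and 1.65 (SE 0.13 each). Among clock genes the largest adult amplitudes were those of Per2 (2.25, SE 0.17), Dbp (2.23, SE 0.12), Ciart (1.80), Nr1d1 (1.78) and Per3 (1.70), which are clock repressors or clock-driven factors. In aged the same genes had 2.21, 2.07, 1.73, 1.58 and 1.53. Per2 peaked at ZT14.0 in both ages and Nr1d1 at ZT8.4 in adult and ZT8.7 in aged. In the list 17 of 19 members were rhythmic in each age, and 17 in adult and 18 in aged when adjusted over the list alone. The mean of the list had an amplitude of 0.56 in adult and 0.58 in aged (permutation, adjusted p = 0.00045 in each, from an unadjusted 1e-05 that is the smallest the permutations can give).

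**Figure D4:**
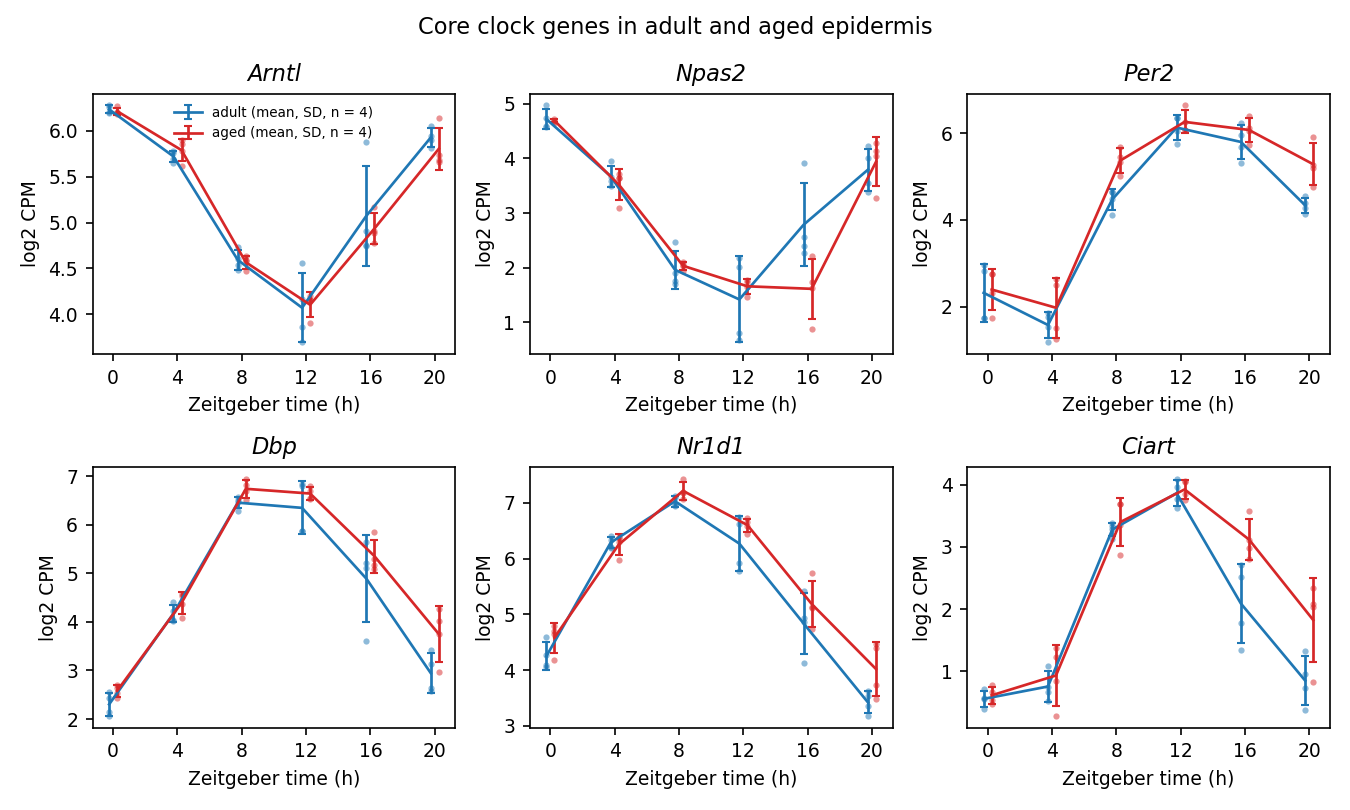
Log2 CPM of Arntl, Npas2, Per2, Dbp, Nr1d1 and Ciart against Zeitgeber time in hours in adult and aged epidermis (points, libraries; lines, mean with SD, n = 4). The amplitude of Arntl is 1.05 in adult and 1.06 in aged.

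Outside the clock, large adult amplitudes were found in Lrat, which stores retinol as esters (1.73, SE 0.53; 13 single libraries each decided its call), the collagen Col19a1 (1.49, SE 0.28) and the tubulin-binding Tppp3 (1.35, SE 0.15). In aged the list of the largest held Fkbp5 (1.24, SE 0.19, peak at ZT16.5), the cystatin Cstdc5 (1.24), the glucocorticoid-induced G protein Rasd1 (1.22) and the adenosine receptor Adora1 (1.21). The calls of Cstdc5 and Adora1 hung on single libraries, and that of Cstdc5 was also lost with the replicate number as a block. In total 2640 genes (14.6%) were rhythmic in adult and 1059 (5.87%) in aged, and 646 in both, where chance gives 155. The test of the difference between ages called 0 genes by edgeR, 0 by limma and 33 by DESeq2, with 1326 at an unadjusted p under 0.05. The smallest adjusted p, 0.0839, was shared by genes that included the splicing factor Hnrnpc (amplitude 0.25 in adult, 0.01 in aged) and Ahsa1, which activates the chaperone HSP90 (0.32 and 0.05). Ly6k, Nudt5 and Entrez100503942 had the same adjusted p. Snord17, Trmt1l, Cryab, Cep19 and B3gat3 followed at 0.107.

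Heat shock genes were rhythmic in adult, with an amplitude of 0.25, a peak at ZT20.9 and an adjusted p of 0.00045 by permutation. In aged the amplitude was 0.04 (adjusted p = 0.799, permutation), and the difference between ages passed (adjusted p = 0.0216, permutation). It did not pass without the adult ZT20 replicate 4 (0.0720) or without all ZT20 libraries (0.0624). At ZT20 the mean of the list was -0.268 and -0.346 in the aged replicates 1 and 2, against 0.207 and 0.116 in the aged replicates 3 and 4 and 0.253 to 0.438 in adult. Without the aged replicates 1 and 2 the difference did not pass (adjusted p = 0.0954, permutation), with an aged amplitude of 0.10 (adjusted p = 0.205, permutation). The unadjusted p of this difference was 0.00212 (permutation). The pair was chosen by its low values on this list, so leaving it out tends to weaken the difference. Of 16 members 13 were rhythmic in adult and 1 in aged, and 15 and 1 when adjusted over the list alone. The chaperone Hsp90aa1 had an amplitude of 0.47 (SE 0.07) in adult and 0.09 (SE 0.07) in aged, and Hspa8 of 0.36 and 0.06 (SE 0.06 each). The cold and temperature responsive list was rhythmic in adult (amplitude 0.14, peak at ZT20.1, adjusted p = 0.0006, permutation), and the difference between ages did not pass (adjusted p = 0.387). As 5 of its 9 members are also in the heat shock list, its rhythm is not independent of that list. Unlike the list mean, its member Cirbp peaked at ZT8.4 with 0.57 (SE 0.08) in adult and had 0.17 (SE 0.07) in aged. The unfolded protein response was rhythmic in adult (amplitude 0.16, peak at ZT21.3, adjusted p = 0.00259, permutation; 0.109 without the ZT20 libraries), with Pdia6 and Calr at 0.33 and 0.38.

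G2/M genes peaked at ZT0.49 in adult with an amplitude of 0.52 (adjusted p = 0.0027, permutation) and at ZT0.87 in aged with 0.45 (0.0332; 0.102 without the ZT20 libraries, and lost without any 1 of 12 libraries). Cenpf, a kinetochore protein, had amplitudes of 0.50 and 0.48 (SE 0.08 each). Of the 28 members 27 were rhythmic in adult and 20 in aged, and 27 and 28 when adjusted over the list alone. S phase genes passed in aged (amplitude 0.39, peak at ZT11.9, adjusted p = 0.00967, permutation) and not in adult (0.26, peak at ZT14.3, 0.109), and the difference between ages did not pass (0.640). In adult at ZT12 the mean of this list was -0.619 in replicate 3, the lowest of all libraries. The other adult ZT12 libraries had 0.537, 0.490 and -0.193, so this group was widely spread. These values do not tell whether the lack of a call in adult rests on replicate 3. The replicative helicase subunit Mcm2 had amplitudes of 0.56 and 0.71 (SE 0.11 each). Glucocorticoid response genes passed in aged (amplitude 0.39, peak at ZT16.6, adjusted p = 0.0116, permutation) and not in adult (0.16, 0.422), and this difference did not pass either (0.640). Tsc22d3, an anti-inflammatory target of the receptor, had amplitudes of 0.77 in adult and 1.16 in aged (SE 0.17 each). The mast cell list passed in adult on 3 tested members (adjusted p = 0.0272, permutation; 0.109 without the ZT20 libraries). YAP/TAZ target genes as a list were not rhythmic in adult (0.746) or aged (0.841).

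**Figure D5:**
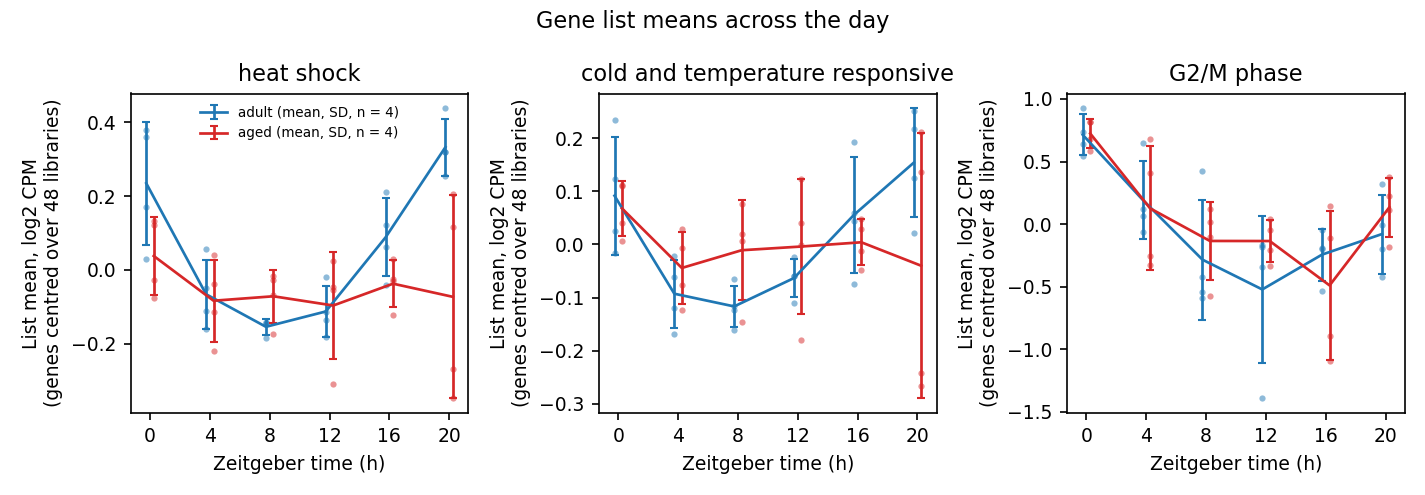
Mean of centred log2 CPM of the heat shock, cold and temperature responsive, and G2/M lists against Zeitgeber time in hours in adult and aged epidermis (points, libraries; lines, mean with SD, n = 4). The heat shock list has an amplitude of 0.25 in adult and 0.04 in aged.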

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

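In this part the tests of genetic background, of clock time at ZT20, of the cell mixture at ZT20 and of the libraries low in heat shock genes were chosen after the result was seen.

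Heat shock genes as a list differed in rhythm between the ages (adjusted p = 0.0216, permutation), with an amplitude of 0.25 in adult and 0.04 in aged. The difference did not pass without the adult ZT20 replicate 4 (0.0720), without all ZT20 libraries (0.0624) or without the aged ZT20 replicates 1 and 2 (0.0954). That aged pair was chosen by its low values on this list. In 51 genes the age effect differed between times by edgeR's test. The adjusted p was 0.0016882 for Snord17 and for Snora81, 0.0032175 for Entrez100503942 and for Snord15a, and 0.005108 for Scarna6. Single libraries far from the other 3 of their group were looked for in 5 quantities over the 12 groups, and 6 were found in these 60 checks, where chance gives about 1 in 20 checks. Arntl stood at 5.8825 log2 CPM in the adult ZT16 replicate 4 (the others 4.75 to 4.91) and at 3.9014 in the aged ZT12 replicate 1 (4.16 to 4.20). It stood at 6.1431 in the aged ZT20 replicate 4 (5.66 to 5.73). The mean of the heat shock list was -0.18533 in the adult ZT8 replicate 3 (-0.146 to -0.141). The mitochondrial ribosomal RNA mt-Rnr2 took 13.873% of counts in the adult ZT20 replicate 1 (16.2% to 16.7%) and 13.609% in the aged ZT0 replicate 3 (15.7% to 15.8%).

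In 28 genes all adult libraries lay apart from all aged libraries, and 1 of 100 splits of the libraries (the real one) gave as many, with 0 in the highest of the others, so chance can be excluded. A difference in genetic background between the adult and aged mice may contribute. Nnt, Wdfy1, Entpd4b and Ide were taken as markers of C57BL/6 substrains, and all 4 passed with a log2 fold change of at least 0.5. Ide is the weaker marker, as 2 adult libraries lay within its aged range, against 0 for Nnt, Wdfy1 and Entpd4b. Background and age cannot be separated by group here, because strain is not given in the sources used here, and Entpd4b shares reads with a near-identical copy. An effect of age on these genes was not tested apart from this and stays open. A difference in background would also enter every other comparison of adult with aged libraries, among them the counts of genes and the list tests for age.

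ZT20 had 3616 genes changed, against 804 at the next highest time. A different mixture of follicle and Langerhans cells stays open, since with the anagen and Langerhans list means as covariates ZT20 had 2.02 times the count of the highest other time (3440 against 1703) and with the follicle stem cell list alone 2.08 times (7237 against 3474), but with all 3 lists 0.338 times (703 against 2083), and the follicle list falls with age, so it may take out an age effect too. A difference in clock time cannot be told apart from no difference, as the clock genes of aged ZT20 libraries read 1.08 h earlier (-1.08 h, exact p = 0.143, n = 4). The aged ZT20 replicates 1 and 2, whose heat shock lists were low (-0.268 and -0.346, against 0.207 and 0.116 in the other two), may carry the higher count. Without them ZT20 had 457 genes, a ratio of 0.5193 to the highest other time, although losing 2 libraries lowered it in most other pairs too: 1161 to 1392 for aged pairs with 1 of the low libraries (4194 without replicates 3 and 4), and 582 to 1365 for adult pairs (2996 without replicates 3 and 4); with 2 surrogate variables, tried earlier, ZT20 had 1975 and ZT0 1947, which decides nothing because a variable separated the ages at ZT20.

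More genes were rhythmic in adult (2640) than in aged (1059). The gap of 1581 genes was reached by 1 of 100 splits (the real one), with 1417 in the highest of the others. In the other splits the age differences of genes stay in the spread, which can lower their counts of rhythmic genes. A share of 1 of 100 is also the smallest possible, so chance is not excluded. A larger spread between aged replicates is argued against, because the median ratio of the spread within groups was 1.025, aged over adult. A lower amplitude in aged may contribute: over 4090 genes rhythmic when both ages were fitted together the median log2 ratio of amplitudes was -0.2683, with 0.230 as the largest size in the other splits. Over the 646 genes called in each age the median amplitudes were nearly equal, 0.290 in adult and 0.287 in aged, but these genes were chosen by passing in both. An effect of age itself stays open, and the test of the difference called 0 genes by edgeR (1326 at an unadjusted p under 0.05, 33 by DESeq2, 0 by limma).

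Other splits of the libraries were also counted for each comparison. For the age effect over all times 1 of 100 splits gave as many genes (5976, the highest other 3824). For rhythm it was 1 of 100 in adult (2640, 13) and 1 of 100 in aged (1059, 111). Each time this was the real split, so chance is unlikely. A share of 1 of 100 is the smallest possible here and was not adjusted over the comparisons. Of 35 splits at single times 1 gave as many at ZT0 (804, 0), ZT4 (114, 2), ZT16 (355, 24) and ZT20 (3616, 331). This was the real split, and 1 of 35 is the smallest share this test can give. The share was not adjusted over the times, so the test cannot exclude chance at a single time. At ZT8 it was 2 of 35 (395, the highest other 2210) and at ZT12 8 of 35 (199, 4851), so chance cannot be excluded, and the higher counts point to a structure of the samples other than age. For the age effect differing between times it was 3 of 100 (51, the highest other 563). This share is under 0.05 without adjustment over the comparisons, and other splits gave more genes, so chance is not excluded. The higher counts point to such a structure as well. For the difference of rhythms all 100 splits gave at least the real count of 0, with 2057 in the highest.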

How the results depend on the processing

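The fits without ZT20 or without chosen libraries, without small RNAs, with 2 surrogate variables and with covariates were chosen after the results were seen. Except where a smaller number of libraries or a stricter limit explains a lower count, the cause was not tested. Counts of genes not printed here stayed within 1.5 times their value. At an adjusted p under 0.01 there were 1751 genes higher and 1732 lower with age, 270 at ZT0, 54 at ZT4, 100 at ZT8, 89 at ZT12, 107 at ZT16, 1339 at ZT20, 7 differing between times, 1214 rhythmic in adult and 458 in aged. A log2 fold change of at least 0.5 left 734 and 409, and an amplitude of at least 0.25 left 1088 and 536. Without ZT20 there were 1718 higher, 1754 lower and 3 genes differing in rhythm. With 1 surrogate variable ZT4 had 172, ZT8 689, ZT16 686, age by time 141 and the rhythm difference 1. With 2 they had 327, 241, 1933, 113 and 11, with 1947 at ZT0, 1975 at ZT20, 4502 rhythmic in adult and 2611 in aged. With the anagen and Langerhans covariates ZT0 had 1634, ZT4 400, ZT8 252, ZT12 336, ZT16 1703, rhythm 4295 and 2326, and its difference 11. With the follicle stem cell list as well, ZT0 to ZT20 had 1147, 359, 270, 107, 2083 and 703, and with that list alone 2059, 520, 3474, 2984, 1199 and 7237. Fits to the libraries of one time gave 2332 at ZT0, 23 at ZT4, 149 at ZT8, 8 at ZT12 and 28 at ZT16. DESeq2 gave 176 at ZT4, 334 at ZT12, 686 at ZT16, 659 for age by time and 33 for the rhythm difference. Without the adult libraries low in Ide, ZT0 had 521 and age by time 82. Without the aged ZT20 replicates 1 and 2, ZT20 had 457 and age by time 12. Without the other aged pairs (1 and 3, 1 and 4, 2 and 3, 2 and 4, 3 and 4) ZT20 had 1326, 1392, 1161, 1375 and 4194. Without the adult pairs in the same order, 1 and 2 first, it had 582, 1365, 959, 1216, 942 and 2996. Without the aged pair 1 and 2 the difference of the heat shock rhythm between ages did not pass (adjusted p = 0.0954, unadjusted p = 0.00212, permutation). That pair was chosen by its low heat shock values. Of 15 lists past the test at ZT20 12 still passed in the same direction, and 5 others were gained. Age by time had 29 without a filter, 92 with the stricter one and 28 without small RNAs. With any difference between times in place of the cosine, the test of the rhythm difference is the age-by-time test itself, with its 51 genes. With an estimated correlation 0 of the 12 lists passed for age. Without ZT20 5 of the 12 passed and 1 was gained, and without the aged ZT20 replicates 1 and 2 9 of the 12 passed and 2 were gained. Cfd, an adipocyte protease, reversed from a rise of 0.82 to -0.033505 under the stricter filter (adjusted p = 0.449); no other named gene reversed. With the replicate number as a block the counts were 3070 and 2876 for age and 66 for age by time. The DNA repair list (adjusted p = 0.0542) and the aged rhythm of Cstdc5 (0.0923) no longer passed, and a few other named genes near 0.05 changed sides. Same numbers did not pair (mean correlation -0.0162 within a number and 0.00527 between numbers).

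Leaving out each library in turn gave ranges of 410 to 1067 at ZT0, 50 to 131 at ZT4, 78 to 1179 at ZT8, 78 to 1312 at ZT12, 146 to 621 at ZT16, 1821 to 3886 at ZT20, 11 to 266 for age by time and 0 to 9 for the rhythm difference. Counts that moved by over 1.5 times were as follows. ZT0 had 497, 460 and 504 without the adult replicates 1, 3 and 4 of that time and 410, 475 and 440 without the aged 1, 2 and 4. ZT4 had 50 and 59 without the adult 2 and 4 and 56 and 62 without the aged 2 and 4. ZT8 had 78, 1179, 251 and 149 without the adult 1 to 4 and 179, 167 and 183 without the aged 1, 3 and 4. ZT12 had 1312, 432, 78 and 99 without the adult 1 to 4 and 124 without the aged 2. ZT16 had 146 and 166 without the adult 1 and 3 and 172, 151 and 621 without the aged 2, 3 and 4. ZT20 had 2113 and 2065 without the adult 1 and 2 and 1821 and 2069 without the aged 1 and 2. Age by time fell to 32 and 19 without the adult ZT0 replicates 1 and 3, to 31 without each of the adult ZT4 3 and 4, to 18 and 29 without the adult ZT8 1 and 3, to 33 without the adult ZT16 1 and to 16, 17, 28 and 18 without the adult ZT20 1 to 4. It fell to 11, 24, 17 and 15 without the aged ZT0 1 to 4, to 33, 29 and 31 without the aged ZT8 1, 2 and 4, to 27 without the aged ZT12 2, to 19 without the aged ZT16 3 and to 16 and 13 without the aged ZT20 1 and 2. It rose to 142 without the adult ZT4 1, to 92 and 202 without the adult ZT12 1 and 2, to 82 without the aged ZT4 4, to 266 without the aged ZT12 3, to 128 without the aged ZT16 4 and to 161 and 241 without the aged ZT20 3 and 4. The rhythm difference rose from 0 to 1 without the adult ZT4 3, ZT8 2 or ZT20 1 or the aged ZT8 2, to 3 without the aged ZT4 4, to 7 without the aged ZT12 3, to 9 without the aged ZT16 1 and to 8 without the aged ZT20 3. Age over all times stayed between 2787 and 3379 higher and 2660 and 3260 lower, and rhythm between 2144 and 2805 in adult and 851 and 1165 in aged. Of the list calls for age, DNA repair was lost without any 1 of 27 libraries (adjusted p up to 0.102), glucocorticoid response without any 1 of 24 (up to 0.0834), the antimicrobial list without any 1 of 20 (up to 0.0852) and the Hippo list without the adult ZT16 1 (0.0558). S phase was gained without any 1 of 18. Of the list rhythms, G2/M in aged was lost without any 1 of 12 libraries (up to 0.110) and mast cell in adult without the adult ZT8 1 or 2, ZT12 1 or ZT20 2 or 4 (up to 0.0615). The difference for heat shock was lost without the adult ZT20 4 (0.0720). Among genes named above, Cry1 lost its age effect without any 1 of 33 libraries (up to 0.0823), Cstdc5 its aged rhythm without the aged ZT0 2 or 3 or ZT12 4 (up to 0.544) and Adora1 without the aged ZT20 2 (0.0989).

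In counts simulated at this depth and number of libraries, with genes drawn independently, 56% of genes were recovered at 1.25-fold over all times and 26% at one time.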

Other observations

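The tests in this part on the clock and on temperature were chosen after the results were seen.

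Lists that did not pass the camera test over all times also held genes that changed with age. Of basal keratinocyte genes 4 of 18 rose and 1 fell, with 6 and 1 when adjusted over the list alone (camera adjusted p = 0.134). The stem cell factor Trp63 rose by 0.18 (SE 0.04) and Krt14 by 0.31 (SE 0.10), and Sncg fell by 0.65 (SE 0.09). The basement membrane and extracellular matrix list had rises of the anchoring collagen Col7a1 (0.38, SE 0.08) and the laminins Lama3 (0.19) and Lama5 (0.23; adjusted p = 0.0506 without the aged ZT16 replicate 4), and 0 falls of 19. Of 21 oxidative stress and NRF2 genes 5 fell and 0 rose (camera adjusted p = 0.0704), among them Cbr3 (0.32), Cat (0.33, catalase) and Gstm1 (0.43). The stress keratin and wound list went both ways (3 of 19 higher and 3 lower), with Hbegf up by 0.79 and Sprr1a down by 0.85. In the TGF-beta and BMP list Skil rose by 0.33 (SE 0.05), and Ltbp1 and Id2 fell by 0.89 and 0.50, among 4 rises and 5 falls of 19. S phase genes passed for neither side, with Tyms up by 0.16 and Pola1 by 0.21 (camera adjusted p = 0.0536).

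Among cell types, the neutrophil genes Hdc and Ngp rose by 1.32 (SE 0.21) and 1.17 (SE 0.38), with 4 of 8 members higher (camera adjusted p = 0.258). In the macrophage list the phagocyte marker Cd68 rose by 0.75 (SE 0.17) and Apoe fell by 0.33, among 2 rises and 2 falls of 15. The melanocyte list held Gpnmb, which rose by 1.16 (SE 0.22; 2 higher and 1 lower of 13), and the T cell list held Thy1, which rose by 0.71 (SE 0.12), while Trbc1 fell by 0.27 (1 higher and 2 lower of 20). Of 20 Langerhans cell genes only Mfge8 passed, with a fall of 0.63, and 0 passed when adjusted over the list alone. The giant muscle genes Ttn and Neb rose by 0.72 and 0.54, and Mylpf fell by 0.22. The endothelial Lyve1 and Esam rose by 0.69 and 0.51, the Schwann cell list held a rise of Ncam1 (0.61), and the Merkel cell list rises of Syt1 (0.48) and Insm1 (0.35). Nsdhl fell by 0.21 (SE 0.05) in the cholesterol list (1 higher and 6 lower of 21), and Pfkp rose by 0.25 (SE 0.04) in the glycolysis list. In the anagen list Krtap16-1 fell by 2.06 (SE 0.58; adjusted p = 0.0527 without the adult ZT4 replicate 2) and in the sebaceous list Cyp4f39 by 0.31 (SE 0.09), with 0 rises in either. In the dermal fibroblast list 2 of 19 rose, Thy1 and Sparc (0.38), and 2 fell, Fn1 by 0.56 (SE 0.14) and Col6a1 by 0.47. In the remaining lists Fasl (cytotoxic cells) rose by 0.67, Bpgm (erythroid cells) by 0.13 and Hmmr (G2/M) by 0.11, each the only member called. In the B and plasma cell list Cd79a rose by 0.68 and Xbp1 fell by 0.13. In the adipocyte list Plin4 and Cfd rose by 0.63 and 0.82 and Pnpla2 fell by 0.21, but Cfd had -0.03 under the stricter filter (adjusted p = 0.449). In the p53 list 3 of 17 rose, with Plk2 at 0.34, and Sesn2 fell by 0.16. In the MHC class I list H2-T23 and Tapbp fell by 0.16 and 0.12 and Psmb9 rose by 0.18. Several of these calls hung on single libraries: Mylpf was lost without any 1 of 20, Sesn2 of 16, Hmmr of 9 and Fasl of 5 (adjusted p up to 0.0650, 0.0704, 0.0625 and 0.0582), and Xbp1 without the adult ZT12 replicate 3 (0.0561). For the sebaceous list the median was 0.11 and the mean 0.04 while camera ranked it as lower, and the median, mean and test also differed in sign for the B and plasma cell, p53, TGF-beta and BMP, and cold and temperature lists.

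A delay of the clock in aged mice was tested as a hypothesis. Of 17 clock genes rhythmic in both ages 15 peaked later in aged, by a mean of 0.58 h (SD 0.55 over genes), and the permutation p of the mean shift was 0.0323 over 10000 permutations, so a delay may exist. Per1 had the largest shift, 1.99 h later, and Per2 had -0.02 h. Without the ZT20 libraries Per1 had -0.06 h and Per2 -0.57 h. The ZT20 libraries could also carry the delay, since without them the mean shift was 0.3175 h with 12 genes later (permutation p = 0.490), which leaves this open. The values of that permutation were not centred per age, unlike those with all libraries, so the p-values cannot be compared. The clock time read from each library differed by -0.38 h, aged minus adult (permutation p = 0.130). The adult ZT16 replicate 4 had the largest offset from its sampling time, 3.26 h, against a median size of 0.39 h, so it weighs on this difference.

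A lower temperature of the mice behind the aged ZT20 replicates 1 and 2 was also tested as a hypothesis, because Cirbp and Rbm3 are induced by cold and heat shock genes by heat. Their mean was 6.91 and 6.87 log2 CPM in these libraries, against 6.36 and 6.16 in the other two aged libraries and 5.58 to 5.71 in adult. As deviations from group means over 48 libraries, it fell as the heat shock list rose (Pearson r = -0.523, permutation p = 0.0277; Spearman rho = -0.405, permutation p = 0.0328). Without the 2 libraries farthest from the median r was -0.460 (p = 0.0727 by permutation), and without the 2 low libraries it was -0.4385 (p = 0.0806 by permutation). Over these 3 fits the adjusted p was 0.0806 for each. A temperature difference may contribute, but the values do not decide it, and body temperature was not analysed here.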
